A study of Homo sapiens with 6 samples.

How the data were processed

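RNA sequencing was done on human PBMCs cultured for 10 days in 3 groups of 2 libraries: control, IL-4 with anti-CD40, and IL-4 with anti-CD40 and arctigenin. Groups were taken from the treatment label of each sample. The labels give no donor, batch or replicate number, so replicates were numbered in the order of deposition, a number that names a library and does not tie it to a donor. The labels name polyadenylated RNA as the molecule and a total RNA kit in the protocol, which can both be true.

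The deposited table holds TPM for 39037 Ensembl gene identifiers in 6 columns. Kallisto and DESeq2 are named in the submitters' processing notes with the build GRCh38, without versions. The annotation release, filters and the step from transcripts to genes are not given in the sources used here. Each TPM column as deposited sums to 1000000, so a rise of abundant transcripts lowers all others, and no depth is kept. No confidence interval that needs counts was given. The unit was checked on the values. An entry of exactly 0 can be a failed estimate: genes usually expressed in blood, such as IER3 and HSPA1B, were listed at 0 in all 6 libraries, so that such genes are reported as listed at 0.

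Names came from a table of gene names and from GENCODE release 29 (GRCh38), after removal of version numbers: 34692 identifiers had a name and 4345 did not. The latter held 5.18 to 7.01% of TPM in a library. Coordinates are those of GENCODE release 29, whose release may differ from the one the authors used.

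TPM were analysed as log2(TPM + 1) with a pseudocount of 1. Genes with at least 1 TPM in at least 2 libraries were kept (15472). One linear model with 3 group means was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, 3 residual and 4.51 prior degrees of freedom), giving 3 two-sided comparisons with Benjamini-Hochberg adjustment and a threshold of 0.05. Lists of genes, 26 in number, were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, with adjustment over the 25 lists of a comparison. Calls were repeated with an estimated correlation, which left 0 of them in any comparison, and with fry, which tests whether a list moves on balance and does not compare it with other genes. The estimated correlation rests on 3 residual degrees of freedom, and its power was not tested. It left uncalled even the IL-4/STAT6 targets after stimulation, with 29 of 29 estimates positive, so a call lost with it does not show an unchanged list. Correlation and covariance between comparisons were set against simulated unchanged groups, and overlaps against the number for independent lists. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.

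The fit was tested on simulated data for arctigenin against stimulation, with 200 of 15472 genes changed in each of 10 simulations. It recovered 0.8% of genes changed 2-fold, 28.6% of 4-fold, 75.4% of 8-fold and 92.2% of 16-fold changes, with no wrong sign. Of the calls made, 6.19% were of unchanged genes, somewhat above the threshold of 0.05. Noise was simulated independently for each gene and library, and 3392 genes had an unadjusted p under 0.05 in the real comparison. Recovery depends on the share of changed genes, so these percentages may not hold for the data.

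Named genes follow a rule. In each comparison they are the 10 largest changes in each direction among genes past the threshold whose groups did not overlap and whose higher mean was at least 5 TPM, plus genes chosen beforehand such as IGHE, and the members of each list with the largest moderated t. Variable, diversity and joining segments, Y-linked genes, XIST, genes without an approved name and genes commonly deleted in some people were not named. List members named because they passed, GAPDH, FCER2 and CCL17 with arctigenin and a few others described beyond the rule were chosen after their values were seen. The groups, tests, lists and this rule were set before the data were examined.

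TMM factors were computed on TPM, as a scaling only, by the published formula. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, TMM rescaling, median-of-ratios rescaling, quantile normalization, TPM without immunoglobulin and mitochondrial genes, no trend, robust fitting, a fit of only the compared groups and leaving out each library in turn. Chosen after the data were seen were the sign of the third principal component as a term, only identifiers with a name, an adjusted p of 0.1, and camera under rescaling. No analysis of depth, donors or isoforms was possible from these values.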

Results

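Gene expression was measured by RNA sequencing in human peripheral blood mononuclear cells (PBMCs), the lymphocytes, monocytes and rarer leukocytes isolated from blood. The study concerns allergy. It used IL-4 together with an antibody against CD40, a pair of signals that directs B cells to switch toward IgE, and arctigenin, a plant lignan. Of 6 libraries, 2 came from control cells, 2 from cells given 100 ng/mL IL-4 and 1 µg/mL anti-CD40, and 2 from stimulated cells that also received 10 µg/mL arctigenin, all after 10 days of culture. The deposited values are TPM, a measure of relative abundance, so each library sums to 1000000 and the sequencing depth is unknown. Between 13670 and 15123 gene identifiers reached 1 TPM in a library. Values are mean ± SD over n = 2 libraries, and fold changes are on the log2(TPM + 1) scale, which understates the change of genes of low abundance. The labels do not say whether the 2 libraries of a group came from separate donors or cultures, so the p-values measure the spread between these libraries, which may be technical. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, and the adjusted p-values below come from the limma model.

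Several of the largest rises after IL-4 and anti-CD40 were in known targets of IL-4. F13A1, the A subunit of coagulation factor XIII, rose from 0.494 ± 0.305 to 536 ± 18.3 TPM (log2 fold change 8.50, SE 0.42, limma adjusted p = 0.000849). ALOX15, the 15-lipoxygenase induced by IL-4 in monocytes, rose from 0.158 ± 0.0355 to 232 ± 86.8 TPM (7.60, SE 0.45). The chemokines CCL13 and CCL17 rose with them. CCL13 went from 15.0 ± 13.9 to 1656 ± 211 TPM and CCL17, a ligand of CCR4 on T helper 2 cells, from 44.1 ± 41.6 to 2229 ± 1063 TPM. Of 15 inflammatory genes tested 3 fell, among them IL1B, from 24.6 ± 12 to 0.748 ± 0.303 TPM (log2 fold change -3.80, SE 0.45, adjusted p = 0.0126), and the neutrophil chemokine CXCL8.

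In this comparison, 216 of 15472 genes passed an adjusted p of 0.05, 133 higher and 83 lower, and 2101 had an unadjusted p under 0.05. Of the 216, 17 were identifiers without a name, which can repeat the values of another identifier. Variable, diversity or joining segments of immunoglobulin or T cell receptor genes made up 12. Over all tested genes, both libraries of one group lay above both of the other in 43.3%, which chance gives for 33.3%. Besides the genes above, the largest rises were in RNASE1, a secreted ribonuclease (log2 fold change 8.40), CCL23 (6.69), the extracellular nuclease DNASE1L3 (6.14), the fatty acid binding protein FABP4 (5.67) and the protease inhibitor TFPI2 (5.05). CCL26, eotaxin-3, was listed at 0 in both control libraries and at 335 ± 43.2 TPM after stimulation (adjusted p = 0.000849). The largest falls were in CHIT1 (-5.12) and CHI3L1 (-4.39), a chitinase and a related protein of inflammatory macrophages, in SPARC, a matrix protein (-5.09), and in ADAMDEC1 (-4.71). They continued with the transcription factor BHLHE41 (-3.61), the prostaglandin D2 synthase PTGDS (-3.56), MMP7 (-3.43) and CASP4LP (-3.40), a pseudogene that can share reads with its relatives. Adjusted p-values of these named genes lay at or below 0.0384.

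**Figure D1:**
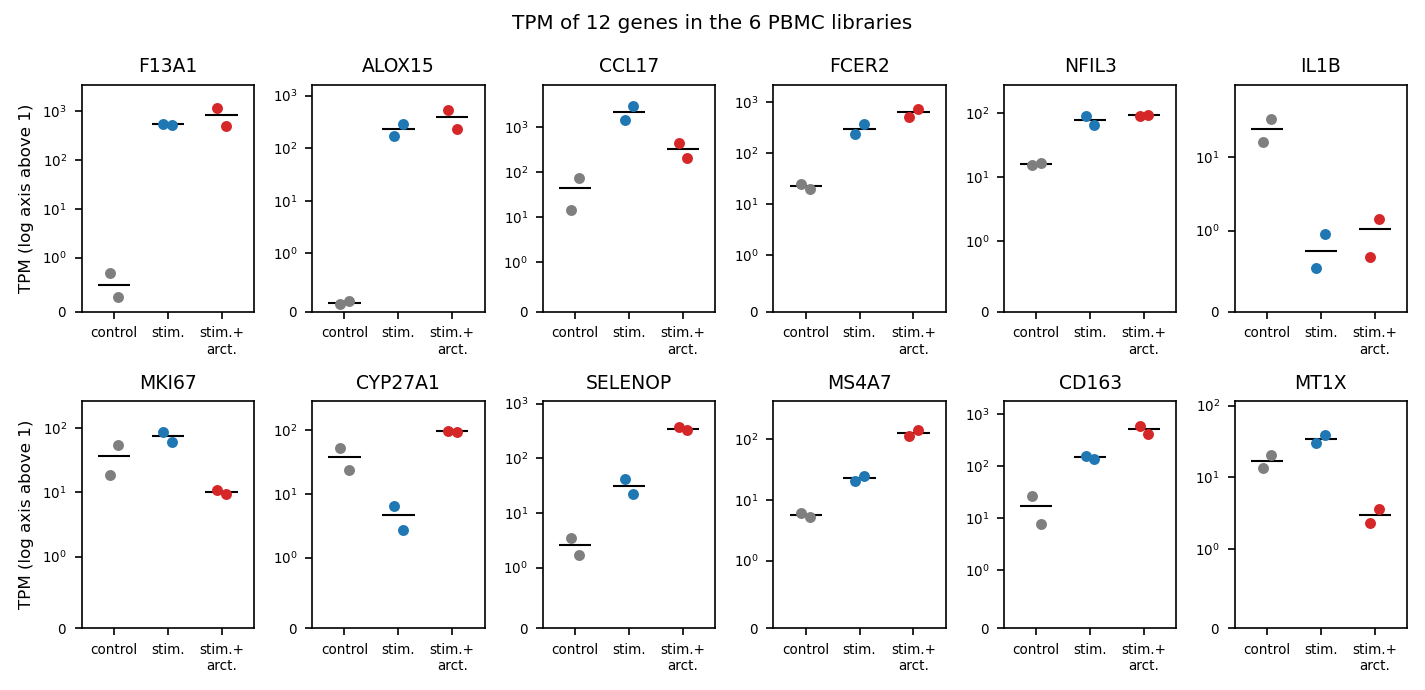
TPM of 12 genes in each of the 6 PBMC libraries, on an axis that is logarithmic above 1 TPM and linear below; points are libraries and bars are group means of 2. F13A1, ALOX15, CCL17, FCER2 and NFIL3 were higher after stimulation with adjusted p under 0.05, MT1X was lower with arctigenin, and CYP27A1, SELENOP and MS4A7 were higher; MKI67 and CD163 did not pass the test of arctigenin against stimulation alone.

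Of the gene lists, the 29 targets of IL-4 and STAT6, the transcription factor it activates, gave the clearest result. 19 rose and none fell over all genes tested, 28 rose when adjusted over the list alone, and the median log2 fold change was 2.90 (camera adjusted p = 2.43e-48, adjusted p = 0.171 with an estimated correlation). FCER2, the low-affinity IgE receptor CD23, rose from 22.6 to 306 TPM, and MAOA rose from 0.688 ± 0.0935 to 42.5 ± 0.580 TPM. Of 26 NF-kB and CD40 targets, 2 fell, the inhibitor NFKBIA (log2 fold change -1.54) and the superoxide dismutase SOD2 (-1.72), and 22 had a negative estimate (camera adjusted p = 0.000137, adjusted p = 0.346 with an estimated correlation). Of 15 inflammatory cytokines and chemokines, 3 fell, IL1B, CXCL8 and CCL20 (camera adjusted p = 0.000513, adjusted p = 0.362 with an estimated correlation). IL10 rose (2.58, SE 0.37), the only one of 18 T helper cytokines and receptors to pass over all genes, in a list with a negative median of -0.88 (camera adjusted p = 0.0107, adjusted p = 0.362 with an estimated correlation).

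Markers of cell types moved as well. Of 18 B cell markers 4 fell, FCRLA (-2.55), FCRL1 (-2.79), BANK1 (-1.91) and TCL1A (-1.89), and 17 had a negative estimate (camera adjusted p = 7.72e-07, adjusted p = 0.362 with an estimated correlation). Of 22 monocyte and macrophage markers, CD163 (3.26), AIF1 (2.33) and MS4A7 (1.82) rose and none fell over all genes, with 8 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.113). The list's median of -0.10 and mean of 0.17 differed in sign, and the median turned positive under median-of-ratios rescaling and quantile normalization. The dendritic cell list also went both ways, with CD1E higher (2.78) and IDO1 (-3.04) and CCR7 (-1.73) lower (camera adjusted p = 0.360). The basophil and mast cell list was lower, with HDC, the histamine-forming enzyme, at -2.42 (camera adjusted p = 0.000527, adjusted p = 0.346 with an estimated correlation). The T cell list had a median of -0.35, with TCF7 lower (-1.81; camera adjusted p = 0.0191, adjusted p = 0.362 with an estimated correlation). GNLY fell among the NK and cytotoxic markers (-2.77), FCRL5 among the plasma cell markers (-2.86), and neither list was called (camera adjusted p = 0.939 and 0.560). Of the 20 interferon-stimulated genes, IFIT1, IFIT2 and IFIT3 fell (-2.28, -2.08 and -2.20; camera adjusted p = 5.15e-05, adjusted p = 0.375 with an estimated correlation).

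All 30 proliferation genes had a positive estimate, with a median of 1.04, and 0 passed over all genes or over the list alone in limma, where 2101 of all genes had an unadjusted p under 0.05 (camera adjusted p = 3.39e-14, adjusted p = 0.375 with an estimated correlation). The control libraries differed widely: the median log2(TPM + 1) of the list was 4.41 and 5.79 in control and 6.45 and 6.02 with stimulation. In the glycolysis and hypoxia list EGLN3, a prolyl hydroxylase induced by hypoxia, rose from 5.28 ± 2.46 to 64.4 ± 1.85 TPM (camera adjusted p = 3.63e-07, adjusted p = 0.362 with an estimated correlation). The mitochondrially encoded genes had a median of -0.62 with none past the threshold (camera adjusted p = 0.00502, adjusted p = 0.561 with an estimated correlation). 6 further lists were called upward by camera, those of class switch machinery, the unfolded protein response, cholesterol synthesis, platelets and erythroid cells, metallothioneins and class II antigen presentation. Their medians lay between 0.27 and 0.97, and their adjusted p with an estimated correlation was at least 0.346.

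IGHE, the gene of the IgE constant region (ENSG00000211891, chromosome 14, 105597691 to 105601728, GRCh38), was listed at 0 in all 6 libraries and could not be tested. In the class switch list NFIL3, a transcription factor that responds to IL-4, rose from 15.6 ± 0.785 to 77 ± 18.6 TPM (log2 fold change 2.21, limma adjusted p = 0.0174). None of the 8 tested immunoglobulin heavy chain constant genes passed (camera adjusted p = 0.939). IGHG1 stood at 88.2 ± 31.2 and 163 ± 58.3 TPM and IGHM at 606 ± 25.5 and 304 ± 112 TPM. These genes are near-identical in part and can share reads. Fewer genes passed when any 1 library was left out (42 to 79 of them) or when the arctigenin libraries were left out of the fit (55), and 0 passed with no filter on low values, while the sign of the third principal component as a term gave 478, of which 45.2% were higher against 61.6% of the 216. Median-of-ratios rescaling moved the median log2 fold change of all genes by 0.21 in this comparison and by -0.13 in that of arctigenin with stimulation alone, and camera tests compare a list with the other genes.

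With arctigenin added to the stimulus, few genes passed the test, and those that rose included CYP27A1, SELENOP and MS4A7. CYP27A1, the sterol 27-hydroxylase, rose from 4.61 ± 2.74 to 95.5 ± 0.514 TPM (log2 fold change 4.19, SE 0.48, limma adjusted p = 0.0310). SELENOP, the secreted selenium carrier, rose from 31.6 ± 13.6 to 349 ± 31.0 TPM, and MS4A7, a membrane protein of macrophages, from 22.5 ± 3.01 to 126 ± 19.7 TPM. Of 6 metallothioneins, which bind metals, MT1E, MT1G and MT1X fell, MT1X from 34.1 ± 6.26 to 2.96 ± 0.943 TPM. All 30 proliferation genes were estimated lower, although none passed alone over all genes.

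Only 32 genes passed an adjusted p of 0.05 in this comparison, 16 higher and 16 lower, each with an absolute log2 fold change of at least 2.4, while 3392 had an unadjusted p under 0.05. A term for the sign of the third principal component, added after the data were seen, gave 815 genes, which included all 32. The other named genes that rose were SPARC (log2 fold change 3.26), the potassium channel KCNJ5 (3.23), CYP1B1, a target of the aryl hydrocarbon receptor (3.06), the myeloid receptors CD300LB (2.84) and CD300LF (2.54), and the tetraspanin CD9 (2.53). GLRX5P2, a pseudogene that can share reads with its parent, was listed at 0 in both stimulated libraries and at 7.29 ± 1.38 TPM with arctigenin. The other named genes that fell were IGFBP2, an insulin-like growth factor binding protein (-4.60), the chemokine CCL19 (-3.90), the prostacyclin synthase PTGIS (-3.62), EGLN3 (-3.40), GDF10 (-3.35), PTPN20 (-3.19) and the sphingomyelinase SMPD3 (-3.03). Adjusted p-values of the named genes lay between 0.0233 and 0.0411. Under median-of-ratios rescaling 63 genes passed, 22 higher and 41 lower. The calls rested on all 4 libraries compared: 0 genes passed without stimulated replicate 2 or without either arctigenin library, and 1 without stimulated replicate 1. With no filter on low values 0 passed, without control replicate 1 79 passed, and 698 reached an adjusted p of 0.1.

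Among the gene lists, the proliferation list had the smallest p. Its 30 genes had a median log2 fold change of -2.30; 0 passed over all genes tested and 30 fell when adjusted over the list alone (camera adjusted p = 3.95e-25, adjusted p = 0.329 with an estimated correlation). TYMS, thymidylate synthase, stood at 277 ± 124 TPM with stimulation and 30.1 ± 10.3 TPM with arctigenin (adjusted p = 0.0604), and the replication helicase subunit MCM4 at 180 ± 44.3 and 26.9 ± 8.94 TPM (adjusted p = 0.0650). In control cells they stood at 115 ± 51.8 and 89.7 ± 42.6 TPM. Of the 6 tested metallothioneins 3 fell over all genes and 6 over the list alone, with a median of -3.10 (camera adjusted p = 7.37e-10, adjusted p = 0.306 with an estimated correlation). MT2A stood at 38.1 ± 7.63 and 3.73 ± 0.648 TPM (adjusted p = 0.0541). Metallothionein genes are near-identical copies whose reads can be split between them. In the glycolysis and hypoxia list EGLN3 fell over all genes and 12 of 21 genes over the list alone, with a median of -1.11 (camera adjusted p = 6.54e-08, adjusted p = 0.329 with an estimated correlation). LDHA stood at 1273 ± 178 and 306 ± 140 TPM, and GAPDH at 3492 ± 1180 and 801 ± 106 TPM (adjusted p = 0.0701 and 0.0727).

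The lists of cell types separated. The monocyte and macrophage list was higher, with a median of 1.5; MS4A7 rose over all genes and 14 of 22 over the list alone (camera adjusted p = 1.67e-07, adjusted p = 0.329 with an estimated correlation). The alarmin subunit S100A9 stood at 103 ± 34.2 and 340 ± 16.0 TPM and the lipopolysaccharide co-receptor CD14 at 34.2 ± 25.0 and 162 ± 52.6 TPM (adjusted p = 0.0697 and 0.0819). Class II antigen presentation was higher (median 0.94; 5 of 11 over the list alone; camera adjusted p = 0.000815, adjusted p = 0.329 with an estimated correlation), as were the basophil and mast cell list (median 0.85, 9 of 9 estimates positive, adjusted p = 0.306 with an estimated correlation) and the B cell list (median 0.55, adjusted p = 0.447 with an estimated correlation). MS4A2, the beta chain of the high-affinity IgE receptor, stood at 1.35 ± 0.910 and 11.9 ± 0.449 TPM (adjusted p = 0.0672). The NK and cytotoxic list was lower (median -0.95; camera adjusted p = 5.13e-06, adjusted p = 0.365 with an estimated correlation), with CD8B, a chain of the CD8 co-receptor, at 222 ± 20.8 and 54.1 ± 23.1 TPM and the protease GZMB at 302 ± 217 and 24.8 ± 17.7 TPM (adjusted p = 0.0697 and 0.0734). So was the T cell list (median -0.76, adjusted p = 0.306 with an estimated correlation), with CD3D at 432 ± 78.9 and 118 ± 34.2 TPM (adjusted p = 0.0650). In the dendritic cell list, LAMP3 and CCL19, genes of mature dendritic cells, fell (log2 fold change -2.40 and -3.90), and the median was -1.51 (adjusted p = 0.365 with an estimated correlation). The plasma cell list had a median of -0.64 (camera adjusted p = 0.00398, adjusted p = 0.306 with an estimated correlation), with CD27 at 60.5 ± 7.12 and 17.0 ± 2.41 TPM (adjusted p = 0.0660). Of its 14 tested members 10 had a negative estimate, JCHAIN only -0.07. The 4 others were PRDM1 (0.13), IRF4 (0.01), POU2AF1 (0.61) and FCRL5 (0.73), so the list did not fall as a whole.

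**Figure D2:**
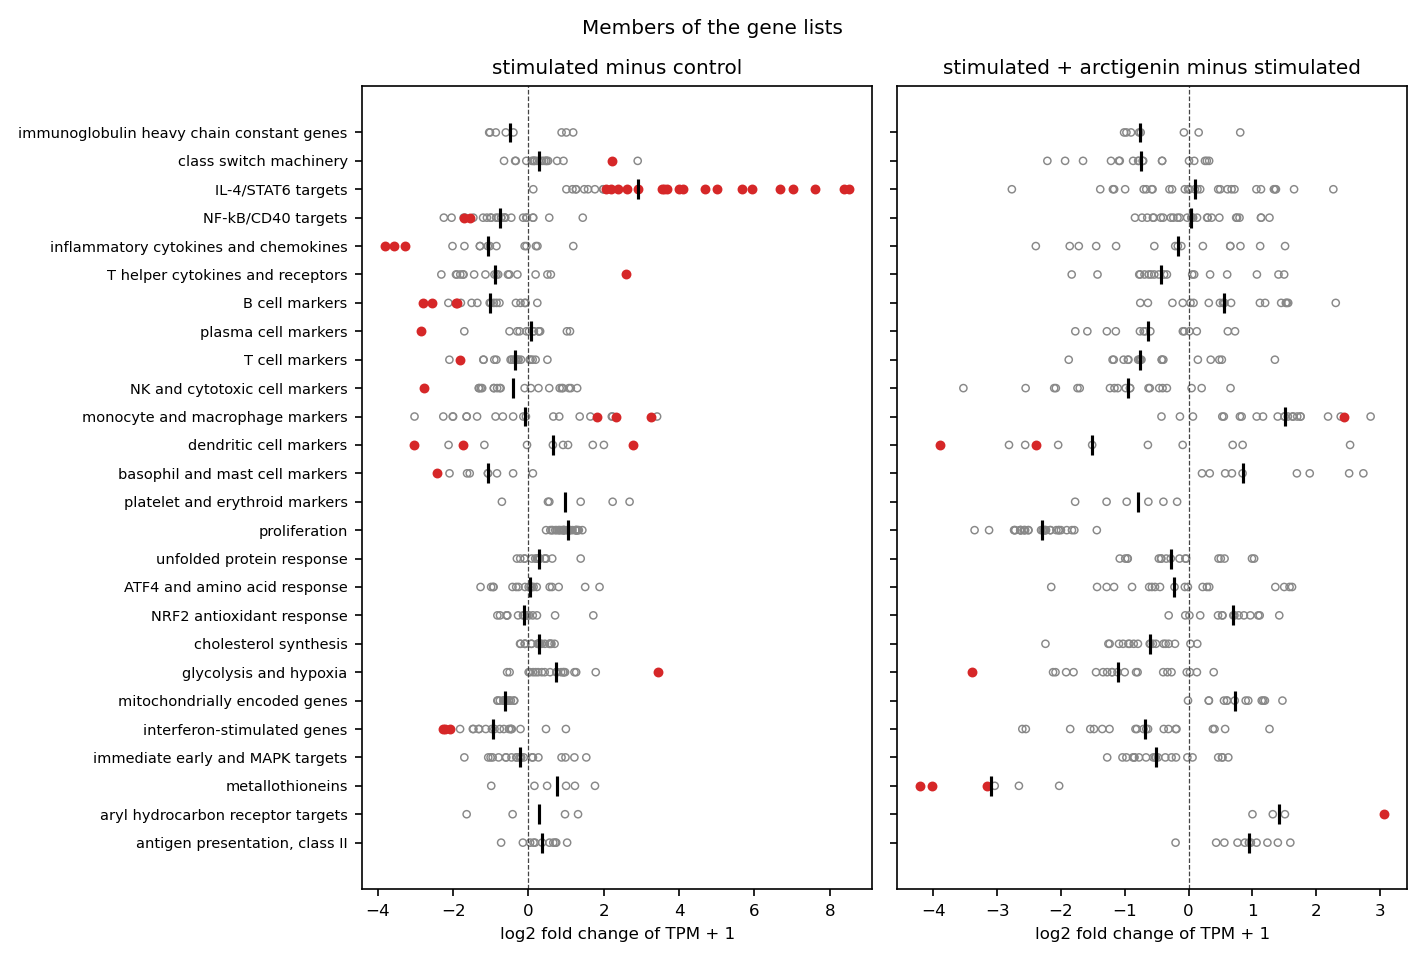
Log2 fold change of TPM + 1 for each tested member of the 26 gene lists, stimulated minus control on the left and arctigenin plus stimulus minus stimulus alone on the right; filled circles have an adjusted p under 0.05, open circles do not, and bars are list medians. The IL-4/STAT6 targets had a median of 2.90 on the left and 0.10 on the right, and all 30 proliferation genes lie below 0 on the right.

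The IL-4 and STAT6 targets showed no joint shift with arctigenin. Of 29 genes 0 passed over all genes, 6 were higher and 3 lower over the list alone, and the median was 0.10 (camera adjusted p = 0.772), with a sign that turned under median-of-ratios rescaling. TGM2, transglutaminase 2, stood at 65.4 ± 10.9 and 333 ± 145 TPM and SOCS1, an inhibitor of cytokine signalling, at 57.8 ± 18.3 and 21.1 ± 3.51 TPM (adjusted p = 0.0666 and 0.0943). FCER2 stood at 306 and 633 TPM and CCL17 at 2229 ± 1063 and 331 ± 176 TPM (adjusted p = 0.141 and 0.108). The NF-kB and CD40 targets had a median of 0.04 (camera adjusted p = 0.904), and its sign turned under both TMM and median-of-ratios rescaling. The class switch list was lower (median -0.75, 6 of 18 over the list alone; camera adjusted p = 0.000154, adjusted p = 0.359 with an estimated correlation), with the exonuclease EXO1 at 24.8 ± 4.28 and 4.67 ± 1.81 TPM and the uracil glycosylase UNG at 41.0 ± 6.87 and 12.6 ± 4.23 TPM (adjusted p = 0.0701 and 0.0821). Immunoglobulin heavy chain constant genes had a median of -0.76, with 0 of 8 past the threshold (camera adjusted p = 0.108), and IGHG1 stood at 163 ± 58.3 and 92.5 ± 15.3 TPM (adjusted p = 0.269).

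5 further lists were called by camera. NRF2 antioxidant genes and mitochondrially encoded genes were higher (medians 0.70 and 0.72, adjusted p = 0.306 and 0.447 with an estimated correlation). Cholesterol synthesis, interferon-stimulated and immediate early genes were lower (medians -0.61, -0.68 and -0.51, adjusted p = 0.365 with an estimated correlation for each). The 4 tested members of the aryl hydrocarbon receptor list, CYP1B1, AHRR, TIPARP and LRRC25, were higher when adjusted over the list alone, too few for camera. Only CYP1B1 passed over all genes. The remaining members, CYP1A1 and CYP1A2, lay below the filter, at most at 0.260 and 0.563 TPM in any library. Not called were the lists of inflammatory cytokines, T helper cytokines, platelets and erythroid cells, the unfolded protein response and ATF4 targets (camera adjusted p at least 0.0660).

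The fold changes of both comparisons were set against each other. They share the stimulated libraries, which by itself favours opposite signs, and the numbers for independent lists below do not allow for this. 9 genes rose with stimulation and fell with arctigenin, among them EGLN3, IGFBP2, PTGIS, SMPD3, GDF10, PTPN20 and CRH, corticotropin-releasing hormone, against 0.138 for independent lists. 7 fell and then rose, among them SPARC and CYP27A1, against 0.0858. MS4A7 and SELENOP rose in both, and 0 genes fell in both (limma; 2101 and 3392 genes had an unadjusted p under 0.05). Across genes, which are not independent replicates, the 2 sets of fold changes had a Pearson r of -0.434, where unchanged groups that share libraries gave -0.500 (simulated range -0.519 to -0.478). The covariance was -0.265 against a simulated -0.100, or -0.140 when each gene's own spread was used, differences of -0.164 and -0.125. With 1 stimulated library used for each comparison, r was -0.103 and -0.188. Differences shared by libraries of the same replicate number enter both sets with the same sign here, which pushes r toward positive values.

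In cells given both the stimulus and arctigenin, RNASE1, F13A1 and SELENOP were higher than in control, and 4 of 20 cytotoxic and 6 of 20 interferon-stimulated genes were lower. RNASE1 rose from 1.30 ± 0.150 to 1440 ± 492 TPM (log2 fold change 9.25, SE 0.51, limma adjusted p = 0.000408), and F13A1 from 0.494 ± 0.305 to 828 ± 478 TPM. SELENOP rose from 2.61 ± 1.28 to 349 ± 31.0 TPM. GNLY, the cytolytic granulysin, fell from 566 ± 36.9 to 46.5 ± 25.3 TPM and the tryptophan-degrading enzyme IDO1 from 89.5 ± 58.4 to 2.50 ± 0.871 TPM.

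In this comparison 487 genes passed, 308 higher and 179 lower, and 2835 had an unadjusted p under 0.05. Of the 487, 63 were identifiers without a name, which can repeat the values of another identifier. Variable, diversity or joining segments of immunoglobulin or T cell receptor genes made up 19. Of the 133 genes raised by stimulation alone, 84 were also called higher here, and of the 83 lowered, 33 were also called lower; both comparisons use the same control libraries, which by itself favours shared calls. Other named genes that rose were ALOX15, CCL23, CCL13, MS4A6A, MS4A4A and the lectin CD209, with log2 fold changes from 6.15 to 8.27, and CCL26, again listed at 0 in control. Other named genes that fell were CHIT1 (-4.81), ZBED2 (-4.20), ADAMDEC1 (-4.10), CHI3L1 (-4.02), the growth factor CSF2 (-3.74), the protease GZMB (-3.63), IL1B (-3.58) and MT1G (-3.52). IGHA1 fell, the only one of 8 immunoglobulin heavy chain constant genes to pass (-1.92, SE 0.36, adjusted p = 0.0370; camera adjusted p = 0.202).

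Of the IL-4 and STAT6 targets 18 of 29 rose (camera adjusted p = 3.13e-31, adjusted p = 0.163 with an estimated correlation), and of the monocyte and macrophage markers 8 of 22 rose, CD163 from 16.8 ± 13 to 501 ± 119 TPM (camera adjusted p = 9.12e-09, adjusted p = 0.197 with an estimated correlation). HMOX1, heme oxygenase, rose in the NRF2 list (log2 fold change 2.59; camera adjusted p = 0.00176), and HLA-DPA1 and HLA-DMB rose in the class II list (1.91 and 1.72; camera adjusted p = 2.56e-07), adjusted p = 0.163 with an estimated correlation for each list. 6 of 20 interferon-stimulated genes fell, IFIT3 by 2.84 (camera adjusted p = 6.53e-11, adjusted p = 0.163 with an estimated correlation), as did 4 of 20 NK and cytotoxic markers, GNLY, PRF1, CTSW and GZMB (camera adjusted p = 4.05e-06, adjusted p = 0.459 with an estimated correlation). 2 of 19 T cell markers fell, CD2 and CD3D (camera adjusted p = 9.44e-08), and 4 of 6 metallothioneins (camera adjusted p = 9.44e-08), adjusted p = 0.163 with an estimated correlation for each list. All 30 proliferation genes had a negative estimate, with 0 past the threshold over all genes and 19 over the list alone (camera adjusted p = 6.53e-11, adjusted p = 0.407 with an estimated correlation). Of the 16 lists that camera called here, none held with an estimated correlation, where the adjusted p lay between 0.163 and 0.561. With 1 arctigenin library left out 13 or 21 genes passed, with 1 control library left out 65 or 148, and 34 with no filter on low values, while the component term gave 1096, of which 52% were higher against 63.2%.

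**Figure D3:**
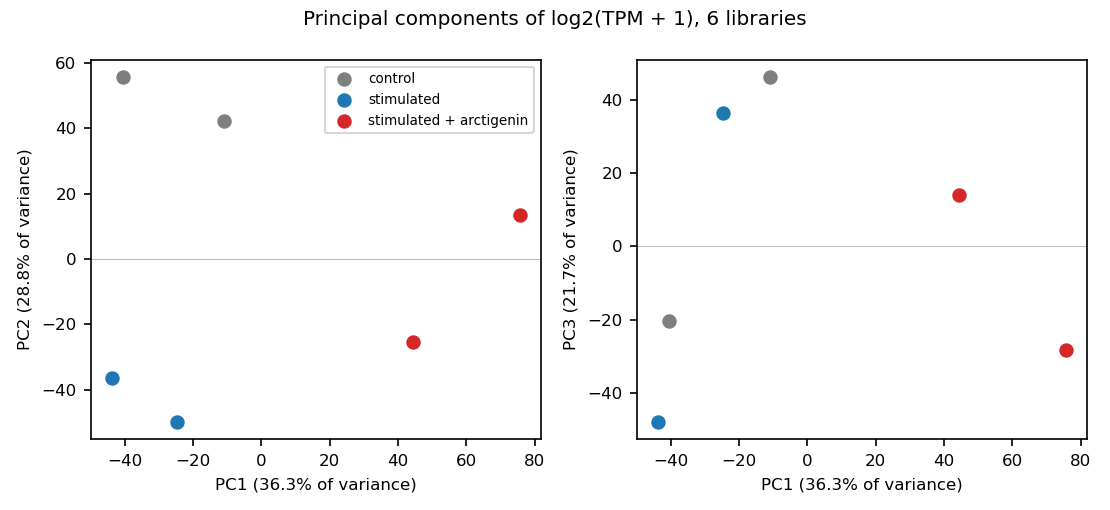
Principal components of log2(TPM + 1) over the 15472 tested genes, the first against the second on the left and against the third on the right, with their share of the variance; each point is 1 of the 6 libraries. Both arctigenin libraries lie at positive values of the first component (44.3 and 75.8) and the other 4 at negative values, and the second separates control from stimulated libraries.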

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

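The component term, the restriction to named identifiers and the adjusted p of 0.1 were chosen after the data were seen. No call of a named gene or list reversed its direction under any alternative run. Counts of changed genes are given for stimulation against control, arctigenin against stimulation and arctigenin against control, with 216, 32 and 487 as reported. They were 0, 0 and 34 with no filter, where more genes enter the adjustment and the prior, and 429, 698 and 1071 at an adjusted p of 0.1. With the sign of the third principal component as a term they were 478, 815 and 1096; that term was chosen from the same values and also parts the libraries by order of deposition, which the labels do not tie to donors. With only the 2 groups compared, and so fewer libraries, 55 and 52 passed in the first 2 comparisons. For arctigenin against stimulation, TMM rescaling gave 49, median-of-ratios rescaling 63 and only named identifiers 163; the cause was not tested. Leaving out each library in turn gave 42 to 79, 0 to 79 and 13 to 434, the lone library being assumed to vary like the others. Pseudocounts of 0.1 and 5, a mean of 5 TPM, quantile normalization, no trend, robust fitting and leaving out immunoglobulin and mitochondrial genes kept all 3 counts within 1.5 times. Of the named genes' calls, 112 of 126 were lost with no filter, and 422 were lost and 334 kept over the leave-one-out fits. Lists called by camera, 17, 17 and 16, became 0, 0 and 0 with an estimated correlation, and fry called 3, 3 and 11. For stimulation, fry called the IL-4/STAT6 targets, the NF-kB/CD40 targets and the basophil and mast cell list. For arctigenin against stimulation it called the plasma cell, metallothionein and basophil and mast cell lists. There the proliferation, macrophage and glycolysis lists, each called by camera, had a fry adjusted p of 0.083. The correlation of -0.434 between comparisons became -0.103 and -0.188 with separate stimulated libraries, and lay between -0.557 and -0.299 with 1 library left out. Separate libraries remove the shared values, but the 2 stimulated libraries differed along the third component (36.5 and -47.9). That difference enters both sets of fold changes with the same sign, which pushes r toward positive values. No analysis paired by donor was possible because the labels give no donor or replicate numbers. A term for order of deposition would equal the component term, so its counts are the 478, 815 and 1096 above. Whether that order pairs libraries is not known. The depth is unknown, and both the 2 libraries per group and the spread between them limit the calls.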

Other observations

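The tests below were chosen after their results were seen, except that of the rescaled proliferation list, which was set out after the pattern was known and before its value was. Ferritin was abundant with arctigenin. FTL, the light chain, stood at 5551 ± 1269 TPM in control, 7829 ± 2257 with stimulation and 30504 ± 7875 with arctigenin, and FTH1, the heavy chain, at 8028 ± 394, 3262 ± 297 and 11861 ± 3252 TPM. Against stimulation the log2 fold changes were 1.97 and 1.84 (SE 0.35 and 0.29, limma adjusted p = 0.0697 and 0.0650), and FTL rose against control (2.45, adjusted p = 0.0146). Both together made up 0.928 to 1.42% of TPM in the 4 other libraries and 3.45 to 5.02% with arctigenin. Genes often used as references for PCR had lower estimates: GAPDH -2.09 and ACTB -1.17 (adjusted p = 0.0727 and 0.127). These genes were singled out after their values were seen.

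The libraries also differed along a direction that the groups do not give. The third principal component, 21.7% of the variance, had positive values in replicate 1 of each group and negative values in replicate 2, which are numbered by order of deposition. Differences between the 2 libraries of a group were correlated across genes between groups, with r of 0.515 for control and stimulated, 0.275 for control and arctigenin and 0.254 for stimulated and arctigenin. The labels name no donor or batch.

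The proliferation list had a median log2 fold change of -2.30 with arctigenin against stimulation alone, with 0 of 30 genes past the threshold over all genes in limma, where 3392 genes had an unadjusted p under 0.05 (camera adjusted p = 3.95e-25, adjusted p = 0.329 with an estimated correlation). Scaling of TPM by a few abundant transcripts is argued against by a median of -2.43 after median-of-ratios rescaling. Fewer T cells alone would lower these genes no further than T cell markers, yet 27 of 30 had a lower estimate than every T cell marker (lowest CD3D, -1.88). The difference between the list medians changed by -1.63 with arctigenin (-1.92 to -1.35 over the 4 pairs of libraries), but it varied by up to 1.45 between libraries of a group (control; 0.364 in the other groups), and the 95% interval from the pooled spread ran from -3.59 to 0.32, so fewer T cells are not excluded; with medians of levels the change was -2.61, against up to 1.75 within a group. A smaller share of cycling cells of any type, and an effect of arctigenin on the cell cycle, remain as hypotheses and may both hold; no cell counts were analysed here.

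The monocyte and macrophage list had a median of 1.5 with arctigenin, with 1 of 22 markers past the threshold over all genes (camera adjusted p = 1.67e-07, adjusted p = 0.329 with an estimated correlation). A larger share of unchanged monocytes and macrophages, in an unchanged mix, would raise all abundant markers by about 1 amount. The scale understates rises of scarce ones, such as VCAN, at 0.309 ± 0.107 and 1.29 ± 0.319 TPM (log2 fold change 0.80). The comparisons that follow therefore test this explanation only in part. The complement genes C1QA, C1QB and C1QC had log2 fold changes of 0.07, -0.43 and -0.14, while CD14 and MS4A7 had 2.38 and 2.43, and the SD over markers (0.841) exceeded the 0.631 that 95% of 10000 simulations with 1 common change stayed under. The changes from separate pairs of libraries, in both possible pairings, were correlated across markers with r of 0.599 and 0.441 (larger permutation p = 0.0404); the lower one is short of the 0.5 set for excluding this explanation. A larger share and a changed state of these cells cannot be told apart here, with 2 libraries per group and markers that are not independent.

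Some named identifiers stood far below the level of their partners. HLA-DRA, whose product pairs with the invariant chain CD74, was listed at 0.229 to 2.70 TPM where CD74 reached 2456 to 6671 TPM. CCL18, a chemokine induced by IL-4 in macrophages, reached at most 2.81 TPM, while ENSG00000278167, an identifier without a name here, went from 1.93 and 6.62 TPM in control to 2502 and 3258 TPM with stimulation (log2 fold change 9.24, limma adjusted p = 0.000849). Of 1215 identifiers without a name and with a mean of at least 1 TPM, 46.2% shared all 6 values, to 4 decimals, with another identifier, against 2.14% of 13486 with a name, which is consistent with unnamed identifiers being copies of named genes that take or split their reads. For IGHE, above 0 in 0 libraries, an assignment of its reads to such an identifier and a lack of transcripts cannot be told apart, since the sequences behind the identifiers were not analysed here.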
